A study of Mus musculus with 8 samples.

How the data were processed

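The series measured polyadenylated RNA in mouse CD8+ T cells from tumors, in 8 libraries. OT-I cells carry a transgenic T cell receptor for an ovalbumin peptide, and B16-OVA is a mouse melanoma line that expresses ovalbumin. Per the labels, naive OT-I cells lacking the transcription factor Zbtb32 and wild-type OT-I cells were transferred together into B6 mice 1 day before the tumor cells were implanted under the skin, and both were sorted from the tumors 30 days later. One pair of groups holds all sorted OT-I cells and the other only the Tim-3+ subset, which the labels call terminally exhausted (Ttex). Each of the 4 groups has 2 replicates, which the labels do not tie to separate animals. The p-values therefore measure the spread between these libraries, as pooled over genes by the test, and that spread may be technical.

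RNA was extracted with TRIzol and libraries were made and sequenced by BGI, per the labels' protocols. The submitters' processing notes name the mm10 build, Trim Galore 0.4.4, Bowtie2, featureCounts, RSEM and DESeq2, without saying which step each served. The authors deposited one table per population. The table of all sorted OT-I cells lists 17495 protein-coding genes with a value per library whose unit the header does not name. The values have the form of FPKM: multiplied by the merged exon length of GENCODE M21 and 1 divisor per library they gave whole reads, and this deposited FPKM divisor was 1.11, 1.24, 0.952 and 0.941 times the protein-coding total in KO-labelled replicates 1 and 2 and WT-labelled replicates 1 and 2. The same table holds the authors' DESeq2 output, that is a mean count, log2 fold changes with standard errors, p-values and adjusted p-values, per the file headers. Further deposited sheets hold rows of that table with an adjusted p under 0.05 (3019 genes) and those changed 1.5-fold with a mean FPKM of at least 0.5 in the higher genotype (387 higher and 1940 lower in KO-labelled libraries). The deposited Ttex table lists 13126 rows with a normalized signal per library, which is gene counts divided by 1 size factor per library. In it, 173 rows stood at exactly 1 step in all 4 libraries and 16 rows summed to 5 steps, as would follow if 1 had been added to every count before division. No fold change or p-value of the authors was used for Ttex cells.

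Whole reads were recovered from both tables to learn the depth. For Ttex cells, 100% of values in each library lay within 0.01 read of a whole number, and for all sorted OT-I cells 99.8 to 99.9% of values of the 13411 genes with a mean under 1000 counts lay within 0.1 read. Recovered totals were 19.3 and 18.7 M reads for the KO-labelled and 20.3 and 21.3 M for the WT-labelled libraries of all sorted OT-I cells, and 53.7 and 51.6 M against 59.2 and 54.7 M in Ttex cells.

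Because neither table holds raw counts, each comparison (KO-labelled over WT-labelled, 4 libraries) was tested with limma 3.58.1 (limma-trend, two-sided) on log2(value + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes needed a mean of at least 1 FPKM, or of at least 10 normalized counts. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. For all sorted OT-I cells limma's prior degrees of freedom were infinite. Each gene's SE was then that of genes at its level, not its own spread between replicates. A gene with unequal replicates can therefore have a very small p-value there. For Ttex cells the prior degrees of freedom were 4.48. Gene lists (15 lists and 9 sets of cell type markers, fixed before the data were examined) were tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 3 tested members. The named genes are Zbtb32, then the 8 largest changes in each direction among called genes with a mean of at least 5 FPKM or 50 normalized counts and no overlap between the genotypes, leaving out unnamed models, pseudogenes and receptor segments. They also include up to 4 called members of each list (or up to 2 by mean where none was called), Tcf7, Havcr2, Pdcd1, Tox, Gzmb, Ifng, Prf1, Slamf6 and Mki67 in any case, and the 5 genes with the smallest adjusted p for a difference between populations. That rule and the main tests were set before the data were examined. The test that picked the last 5 genes was run on recovered reads, a choice made after the data were seen. Coordinates are GENCODE M21 positions on mm10.

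Alternatives chosen before the data were examined covered other scalings, filters, pseudocounts, thresholds, a replicate block, leaving out each library, other list tests and the authors' own calls. After the data were seen, count tests were added on the recovered reads (edgeR 4.0.16 quasi-likelihood, DESeq2 1.42.0 and limma-voom), with centring of each library on the median of the tested genes and a loess correction for transcript GC content. The difference between populations was described as the difference of 2 log2 fold changes, as planned for tables without counts, and tested in an added edgeR interaction fit of all 8 libraries over 11265 shared genes. The 2 tables were normalized separately, so levels were not compared across them except as shares of reads, in a test of under-counting. The tests were checked on simulated libraries with 200 changed genes. Among 9730 simulated genes of all sorted OT-I cells, limma recovered 81.8% of genes changed 2-fold and 19.4% of those changed 1.5-fold, with 8 false calls. Among 12625 simulated Ttex genes it recovered 93.8% of 4-fold, 30.3% of 2-fold and 1.49% of 1.5-fold changes, with 1 false call. The simulation gave all genes of a population 1 common dispersion and no shift between genotypes. Its recovery and false calls therefore need not hold for the real libraries. R 4.3.3 was used.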

Results

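Gene expression was measured in 8 libraries of OT-I CD8+ T cells sorted from B16-OVA melanomas 30 days after the tumor cells were implanted. The comparisons ask what the loss of Zbtb32, a zinc finger transcription factor, changes in all tumor-infiltrating OT-I cells and in their Tim-3+ terminally exhausted (Ttex) subset. Each had 2 libraries labelled knockout (KO) and 2 labelled wild type (WT). Recovered depth was 18.7 to 21.3 M protein-coding reads per library for all sorted OT-I cells and 51.6 to 59.2 M reads for Ttex cells. The count tests on recovered reads, the centring on the median gene, the deciles of transcript length and the interaction test were chosen after the results were seen.

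Zbtb32 RNA itself was not lower in the libraries labelled KO. The gene lies on chromosome 7 from 30589681 to 30598909 (mm10, minus strand). In all sorted OT-I cells it was at 83.9 ± 15.4 FPKM in KO-labelled libraries and 83.5 ± 5.12 FPKM in WT-labelled libraries (SD, n = 2), with 94.9 and 73.0 FPKM against 79.8 and 87.1 FPKM. In Ttex cells it was at 6822 and 5715 normalized counts in KO-labelled libraries against 3976 and 3951 (log2 fold change 0.66, limma adjusted p = 0.183). Which part of the gene was deleted is not given in the sources used here, so a gene-level value need not show the deletion, and it gives no check of the labels. Every direction below is therefore that of the libraries labelled KO against those labelled WT.

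In all sorted OT-I cells the largest change among the named genes was in Ifng, the gene of the effector cytokine interferon gamma, at 24.1 ± 3.53 FPKM in KO-labelled and 285 ± 45.8 FPKM in WT-labelled libraries (SD, n = 2). Its log2 fold change was -3.51 (SE 0.22, limma adjusted p = 1.07e-50, and edgeR adjusted p = 3.06e-11 on recovered reads). Ctse, which encodes the aspartic protease cathepsin E, fell by 2.43 on the log2 scale, from 40.8 ± 2.24 to 6.74 ± 0.32 FPKM (adjusted p = 1.18e-31). Tcf7, the gene of the transcription factor TCF1 that marks progenitor exhausted and memory T cells, rose by 0.83 (SE 0.19), from 11.1 ± 0.665 to 20.4 ± 0.469 FPKM (adjusted p = 0.000202), and Cxcr5 rose by 0.88. Mki67, a proliferation marker, fell by 1.15. Genes used in myeloid cells stood among the largest decreases, namely the complement genes C1qa (-2.05) and C1qb (-2.09), the chemokine gene Ccl8 (-2.28), and the signalling adaptor gene Tyrobp with Wfdc17 (-2.02 and -2.01).

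The remaining gene of the 8 largest decreases under the naming rule was Lars2 (-2.20), which encodes the mitochondrial leucyl-tRNA synthetase. Under the same rule the largest increases were in Tm4sf19 (1.09), Alb (from 3.27 to 7.58 FPKM), Lad1 (0.95), Rrp12 (0.82), Pmel (0.80), Chpf2 (0.80) and Rasa3 (0.78), together with Tcf7. Of these Pmel, Rrp12, Chpf2 and Rasa3 lost the call in 1 of the 4 fits that left out a library, and Slamf6 kept its call in only 1 of them. The exhaustion genes Havcr2 (Tim-3), Pdcd1 (PD-1) and Tox were not called, with log2 fold changes of -0.08, 0.14 and 0.04. The perforin gene Prf1, of the cytotoxic list, was not called either (0.08). The limma adjusted p of these genes was at least 0.695. Gzmb (granzyme B) was at 1176 ± 134 FPKM in KO-labelled and 1729 ± 76.5 FPKM in WT-labelled libraries (SD, n = 2), with a log2 fold change of -0.56 and a limma adjusted p of 0.0524. The authors' deposited DESeq2 output calls it lower (log2 fold change -0.50, adjusted p = 0.0252), as did limma with the replicate block.

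**Figure D1:**
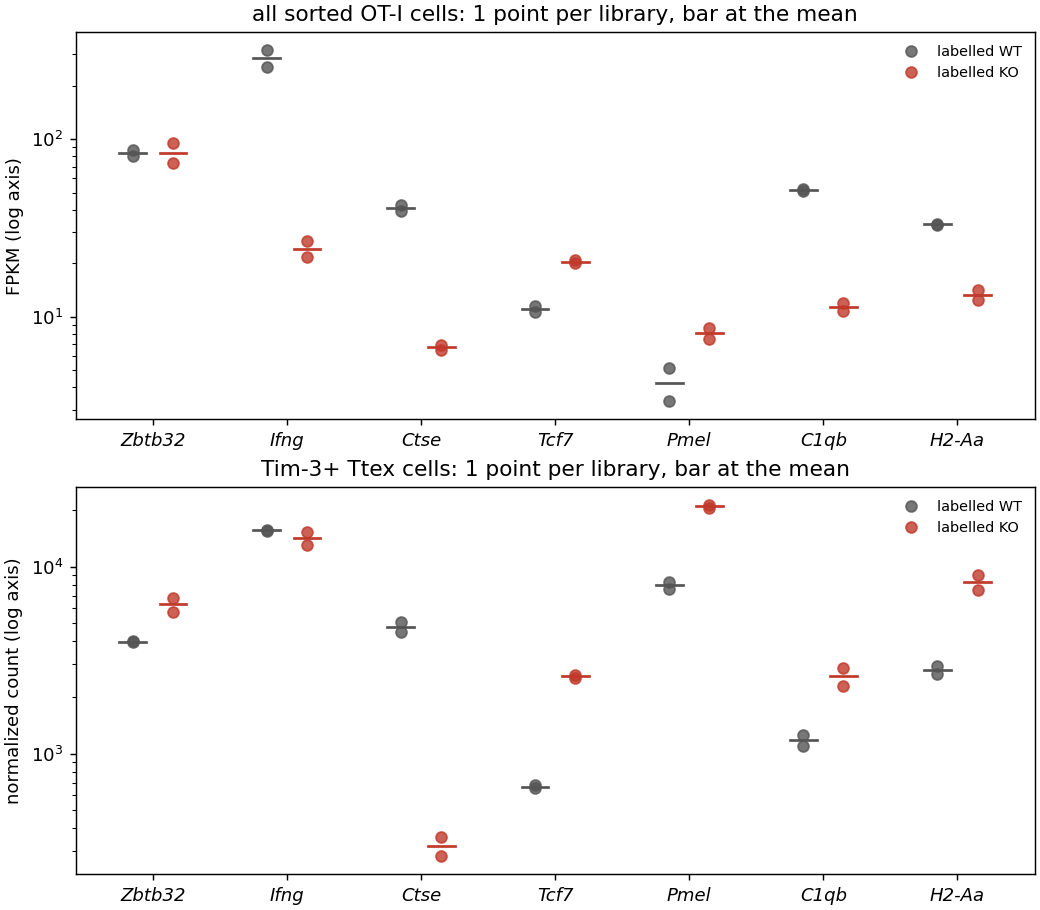
Values of 7 genes in each library, as FPKM in all sorted OT-I cells (top) and normalized counts in Ttex cells (bottom), on log axes; each point is 1 library, red for KO-labelled and grey for WT-labelled, and bars are means of 2 libraries. Ifng separates the genotypes in all sorted OT-I cells (24.1 against 285 FPKM) and Ctse separates them in both populations.

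Of the 30 tested genes for cytotoxic molecules and effector cytokines, 13 were called lower and 1 higher (16 and 1 when adjusted over the list alone), where 30.4% of all tested genes were called lower. Besides Ifng they included Gzma (-1.14), Gzmc (-1.08) and the chemokine gene Ccl1 (-1.26), and Gzmg was higher (0.61). The list was lower than other genes by camera (adjusted p = 0.0322), but not with an estimated correlation (adjusted p = 0.802) and in only 1 of the 4 fits that left out a library. NK-type receptors had 8 of 12 tested genes called lower and 0 higher (8 adjusted over the list alone), with Fcer1g (-1.46), Klra3 (-1.08) and Klrc2 (-0.72) among them, and with Tyrobp, which like Fcer1g is also expressed by myeloid cells (camera adjusted p = 0.00372, and 0.802 with an estimated correlation). Reads of the near-identical Klra and Gzm genes can be split by the counting, so single members are uncertain. In the progenitor exhausted and memory list 7 of 22 tested genes were called higher, Tcf7, Cxcr5 and Slamf6 (0.52) among them, and 5 were called lower, including Foxo1 (-0.55). Adjusted over the list alone the counts were 10 and 7. Its camera direction was up (adjusted p = 0.000901, and 0.802 with an estimated correlation) while its median log2 fold change was -0.04, because the median of all genes lay lower still.

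Of all tested genes 30.4% were called lower, so a count near or under that share does not set a list apart. The T cell receptor signalling list had 8 of 31 genes called lower and 0 higher (6 adjusted over the list alone, 4 lower and 3 higher with centring), among them the phosphatase genes Dusp2 (-1.51) and Dusp5 (-1.44), the kinase gene Fyn (-1.11) and Nfkb1 (-0.98). Immediate-early and heat-shock genes had 8 of 24 lower (8 adjusted over the list alone, 4 with centring), including Jund (-1.67), Ier5 (-1.42), Atf3 (-0.90) and Fosb (-0.75). Oxidative phosphorylation genes had 22 of 35 lower (26 adjusted over the list alone), with Cox6c (-1.02), Ndufb3 (-0.91), Cox5a (-0.90) and Ndufb5 (-0.80). The cell cycle list had 5 of 40 lower, with Mki67, E2f1 (-1.04), Birc5 (-0.63) and Ube2c (-0.60), 2 adjusted over the list alone, and 2 lower and 4 higher with centring. Relative to other genes camera's direction was up for the T cell receptor signalling and cell cycle lists. None of these 4 lists passed the camera test (adjusted p = 0.961, 0.161, 0.0543 and 0.161), but with each library centred on its median oxidative phosphorylation did (adjusted p = 0.000835). With an estimated correlation, and no centring, its adjusted p was 0.802. The shortest and the longest transcripts were lower than others: the median log2 fold change was -0.55 in the length decile with the shortest transcripts, -0.11 in decile 5 and -0.35 in the decile with the longest, which bears on oxidative phosphorylation genes because their transcripts are short.

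No other list passed camera in all sorted OT-I cells, where 30.4% of all tested genes were called lower. Type I interferon response genes had 8 of 24 lower, led by Ifitm3 (-1.64), with Parp14 (-0.65), Isg15 (-0.63) and Rtp4 (-0.57) (8 adjusted over the list alone, 1 with centring, camera adjusted p = 0.753). IL-2 and gamma-chain signalling had 3 lower, the survival gene Mcl1 (-1.32), Pim1 (-0.81) and Il10 (-0.78), and Il4ra higher (0.72) of 26 (the same counts adjusted over the list alone, 3 lower and 6 higher with centring, camera adjusted p = 0.0544, and 0.0404 with centring). Inhibitory receptors and exhaustion transcription factors had 4 lower, among them Id2 (-0.84), Nr4a3 (-0.54) and Nfatc2 (-0.42), and Nt5e higher (0.41) of 25 (4 and 1 adjusted over the list alone, 1 lower and 3 higher with centring, 0.265). Chemokine receptors and adhesion had 5 lower, among them Ccr2 (-0.71), Rgs1 (-0.70) and Zfp683 (-0.50), and Ccr6 higher (0.66) of 23 (5 and 1 adjusted over the list alone, 1 lower and 2 higher with centring, 0.516). Glycolysis and hypoxia had 4 lower, Higd1a (-0.71), Hk2 (-0.62), Gapdh (-0.58) and Ankrd37 (-0.51), and 1 higher of 25 (2 and 0 adjusted over the list alone, 0 lower and 3 higher with centring, 0.161). Cholesterol and fatty acid synthesis had 4 lower of 26, among them Scd2 (-0.55, with overlapping genotypes and an edgeR adjusted p of 0.209), Stard4 (-0.53) and Acaca (-0.43) (4 adjusted over the list alone, 1 lower and 4 higher with centring, 0.198). Of the 26 genes near Zbtb32 on chromosome 7, 12 were lower, including Capns1 (-1.52), Usf2 (-1.35) and Upk1a (-1.10), and 2 higher (12 and 2 adjusted over the list alone, 7 and 5 with centring, 0.219). Gata3 (0.15) was the only tested gene of the type 2 list and was not called.

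Markers of other cells moved with the genotype labels in all sorted OT-I cells. Of 19 tested macrophage, monocyte and dendritic cell markers, 16 were called lower and 0 higher in KO-labelled libraries (18 lower adjusted over the list alone), with C1qa, C1qb, C1qc (-1.73), Lyz2 (75.2 to 22.7 FPKM, -1.70) and H2-Aa (-1.26) among them (camera adjusted p = 5.13e-13, and 0.331 with an estimated correlation). All 4 tested red blood cell genes were higher, from 0.61 for Hba-a1 to 1.28 for Hbb-bt (camera adjusted p = 1.56e-08, and 0.331 with an estimated correlation), and reads of these near-identical globin genes can be split between copies. Hbb-bt rested on KO-labelled replicate 1 (6.56 FPKM, against 0.918 in replicate 2). The other 3 are not called in the authors' deposited DESeq2 output (adjusted p = 0.0998 to 0.139). Hbb-bs and Hba-a1 lost the call in some fits that left out a library. Hba-a2 fell under the filter in some of these fits and was not tested there. Of 7 tested melanoma markers 4 were higher, among them Pmel, Tyrp1 (0.62) and Slc45a2 (0.59), and Apoe (-1.49), which macrophages also express, and Mlana (-0.48) were lower (camera adjusted p = 0.0223, and 0.802 with an estimated correlation, passing in 1 of the 4 fits that left out a library). Adjusted over the list alone these counts were the same for both. Other marker sets had at most 2 tested genes or no call: Il1b (-1.18), Foxp3 (-1.10) and Gzma were lower, Cd79b (-0.15), Cd79a (-0.33, lower adjusted over its list alone) and Pecam1 (0.12) were not called over all genes, and none of 4 genes of the sex of the donor differed, with Eif2s3y and Ddx3y present in all 4 libraries.

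In total 3144 of 9574 tested genes passed in all sorted OT-I cells, 235 higher and 2909 lower (limma, adjusted p under 0.05), so 92.5% of calls were lower. The median gene had a log2 fold change of -0.24, and this shift depended on the scaling: it was -0.02 with upper-quartile scaling, where 752 genes were higher and 1181 lower, and with each library centred on its median 849 were higher and 1146 lower. The FPKM divisors were larger than the protein-coding read totals in KO-labelled libraries (1.11 and 1.24 times) and smaller in WT-labelled libraries (0.952 and 0.941 times), which lowers KO-labelled values. EdgeR on recovered reads gave a median of 0.03 over 15925 genes, with 1901 higher and 2526 lower, but it changed the gene set too. Limma on the deposited values without the filter already gave a median of -0.007 over 17495 genes, with 1651 higher and 2636 lower. These medians therefore do not show how much of the shift came from the divisors. After centring 13 of the macrophage markers, 8 of the cytotoxic list, 6 of the NK-type receptors and 9 of the oxidative phosphorylation genes were still lower, 10 progenitor genes were higher and 0 lower, and Ifng (-3.27), Ctse (-2.19) and Tcf7 (1.06) kept their calls. The authors' deposited table calls 3019 genes, 744 higher and 2275 lower. The count of calls fell to 1602 without WT-labelled replicate 1 and to 1929 without KO-labelled replicate 2.

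In Ttex cells 3 genes passed. Ctse was at 319 ± 52.6 normalized counts in KO-labelled and 4759 ± 434 in WT-labelled libraries (SD, n = 2, log2 fold change -3.90, SE 0.19, limma adjusted p = 0.00468). It lies on chromosome 1 from 131638306 to 131675505 (mm10, plus strand). Tcf7 rose from 665 ± 19.3 to 2591 ± 77.9 normalized counts (1.96, SE 0.15, adjusted p = 0.0471), and Pmel, a melanosome gene expressed by melanoma cells, rose from 7923 ± 441 to 21011 ± 509 (1.41, SE 0.12, adjusted p = 0.0471). Tcf7 lies on chromosome 11 from 52252371 to 52283014 and Pmel on chromosome 10 from 128704195 to 128720238 (mm10).

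The genes of exhausted and effector cells below were not called in Ttex cells by the main test. With the replicate block, an alternative that pairs same-numbered libraries, Havcr2 was called. Havcr2, which encodes the Tim-3 used for the sort, was at 10735 ± 132 normalized counts in KO-labelled and 15898 ± 51.8 in WT-labelled libraries (SD, n = 2, log2 fold change -0.57, limma adjusted p = 0.182). The log2 fold change was -0.14 for Ifng, -0.25 for Pdcd1, -0.16 for Tox, -0.24 for Gzmb, -0.10 for Prf1, -0.30 for Mki67 and 0.55 for Slamf6, with adjusted p from 0.354 to 0.775.

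Of 25 progenitor exhausted and memory genes tested in Ttex cells, Tcf7 alone was called over all genes, and 11 were higher and 0 lower adjusted over the list alone (2 higher over all genes with centring, camera adjusted p = 5.31e-11, direction up, and 0.200 with an estimated correlation). Inhibitory receptors and exhaustion transcription factors had 0 of 27 called, with a median log2 fold change of -0.17 (1 lower adjusted over the list alone, camera adjusted p = 0.00377, and 0.328 with an estimated correlation). The most abundant were Lag3 (-0.10) and Pdcd1. Cell cycle genes had 0 of 40 called and a median of -0.12 (0 adjusted over the list alone, camera adjusted p = 0.00462), with Mcm6 at -0.36 and Top2a at -0.30. IL-2 and gamma-chain signalling had 0 of 28 called (1 lower adjusted over the list alone, 0.00838), with Il2rb at -0.32 and Il2rg at -0.18, and T cell receptor signalling 0 of 32 (0 adjusted over the list alone, 0.0224), with Cd3e at -0.02 and Cd8a at -0.08. Oxidative phosphorylation had 0 of 35 called and a median of 0.29 (0 adjusted over the list alone, 6.97e-06), although its most abundant members Atp5b and Atp5a1 stood at 0.00 and -0.09, and genes near Zbtb32 had 0 of 37 called (0.0375), with Fxyd5 at 0.16 and Cox6b1 at 0.46. With an estimated correlation the adjusted p of these 5 lists lay between 0.328 and 0.457. Of the 4 fits that left out a library, inhibitory receptors and IL-2 signalling passed in 3, and T cell receptor signalling and genes near Zbtb32 in 2. The median of the length decile with the shortest transcripts was 0.35 in Ttex cells, against -0.11 in decile 5.

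Markers of other cells were unequal in Ttex cells too, and here the macrophage markers were higher in KO-labelled libraries. Melanoma markers had a median log2 fold change of 1.08 over 15 tested genes, Pmel called over all genes and 14 higher adjusted over the list alone (camera adjusted p = 3.18e-18). Macrophage, monocyte and dendritic cell markers had 0 of 24 called over all genes, 16 higher adjusted over the list alone and a median of 0.93 (camera adjusted p = 8.36e-18). The most abundant were Cd74, at 39832 ± 1385 against 16890 ± 145 normalized counts (SD, n = 2, 1.24, limma adjusted p = 0.0508), and Cst3 (0.94). Red blood cell genes had a median of 2.32 and 5 of 5 higher adjusted over the list alone (2.76e-08), with Hba-a1 at 2.37 and Hba-a2 at 2.44. Neutrophil markers (median 1.59 over 3 genes, 1 higher adjusted over the list alone, 0.0171; Il1b 1.59, Csf3r 2.40) and B cell markers (0.51 over 9 genes, 1 higher, 0.0284; Ighm 0.74, Igkc -0.20) also passed camera. With centring 3 melanoma, 4 macrophage and 1 red blood cell genes were called higher over all genes, Cd74 among them (adjusted p = 0.0456). With an estimated correlation the adjusted p of these 5 sets lay between 0.200 and 0.328, and of the 4 fits that left out a library the neutrophil set passed in 3 and the B cell set in 1.

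The other lists did not pass in Ttex cells, with 0 genes called over all genes in each. Camera adjusted p was 0.106 for cytotoxic molecules (Ccl5 0.30, Nkg7 0.03), 0.368 for NK-type receptors (Klrk1 -0.08, Klrc1 -0.11), 0.706 for glycolysis and hypoxia (Gapdh 0.17, Eno1 0.22) and 0.251 for cholesterol and fatty acid synthesis (Srebf2 -0.25, Acly -0.53). It was 0.197 for type I interferon (Ly6e -0.01), 0.982 for chemokine receptors and adhesion (Itgb2 -0.36, Selplg -0.01), 0.174 for type 2 genes (Gata3 -0.02, Il1rl1 1.12) and 0.787 for immediate-early and heat-shock genes (Hspa8 0.03, Hsp90aa1 0.13). Among marker sets it was 0.136 for CD4 and regulatory T cells (Zbtb7b -0.67, Trat1 0.05), 0.280 for NK cells (Gzma 0.69, Itga2 -0.79), 0.368 for fibroblast, endothelial and epithelial cells (Pecam1 -0.65, Sparc 0.89) and 0.168 for the sex of the donor (Eif2s3y -0.18, Ddx3y -0.18). Adjusted over the list alone, NK-type receptors had 1 higher and 2 lower, the fibroblast set 1 and 1, the NK cell and interferon sets 1 higher each, and the others 0.

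**Figure D2:**
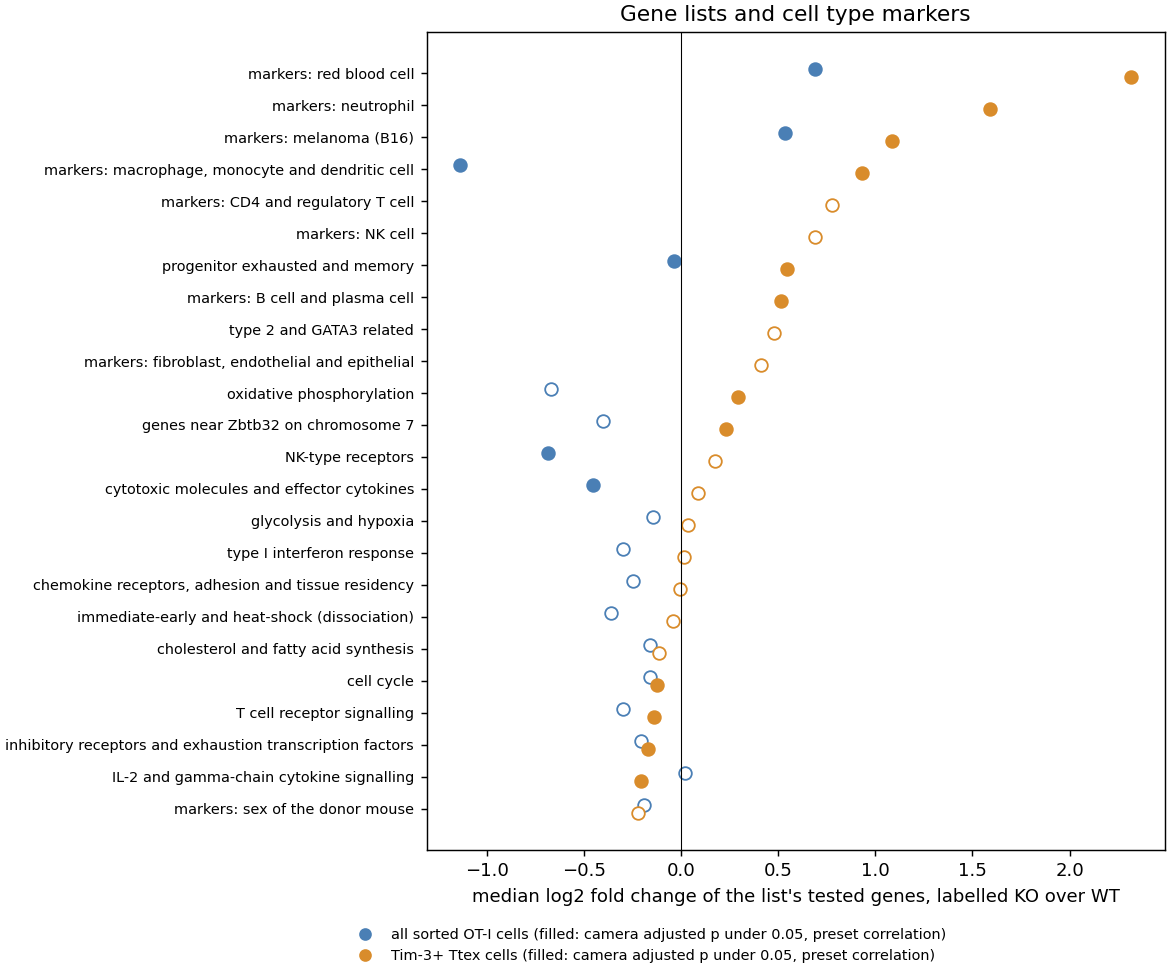
Median log2 fold change (KO-labelled over WT-labelled) of each fixed gene list or marker set in all sorted OT-I cells (blue) and Ttex cells (orange), drawn for lists with at least 3 tested genes; filled points passed camera with a preset correlation. Macrophage markers lie at -1.14 in all sorted OT-I cells and at 0.93 in Ttex cells, and none of the filled points passed with an estimated correlation.

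In Ttex cells 3 of 12559 tested genes passed, 2 higher and 1 lower, and 1789 had an unadjusted p under 0.05 (limma). The count moved with the test: edgeR called 15 and DESeq2 388 on the recovered reads. With a replicate block, which pairs same-numbered libraries, limma called 844, but the labels do not state that these share recipients. The KO-labelled Ttex libraries correlated less with each other (Pearson r of log2 values 0.964) than KO-labelled replicate 2 did with WT-labelled replicates 1 and 2 (0.974 and 0.973). The WT-labelled pair stood at 0.990. The small number of calls therefore does not show a weaker effect in Ttex cells. Leaving out KO-labelled replicate 1 or 2 left 0 limma calls (2306 and 3611 genes at an unadjusted p under 0.05), and leaving out WT-labelled replicate 1 or 2 gave 26 and 8.

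The comparison of both effects covered 8962 genes tested in each population. Ifng, H2-Aa, C1qb, Plbd1 and Ccl8 had the smallest adjusted p for a difference between populations (edgeR interaction test on recovered reads, adjusted p = 0.000144 for each). Ifng was lower in all sorted OT-I cells and not called in Ttex cells (interaction log2 difference 3.25, SE 0.24). The antigen presentation gene H2-Aa (2.71), C1qb (3.14), the phospholipase-like gene Plbd1 (3.69) and Ccl8 (3.96) were lower in all sorted OT-I cells and had positive values in Ttex cells. Tcf7 had the same direction in both populations with a difference of 0.90 (interaction adjusted p = 0.0254). Across the shared genes the log2 fold changes had a Pearson correlation of -0.156 and a Spearman correlation of -0.227, over genes that are not independent replicates. With edgeR fold changes over a wider set of 11094 genes these were 0.133 and -0.0168. Both genes called higher in Ttex cells, Tcf7 and Pmel, were among the 174 called higher in all sorted OT-I cells (0.0388 by chance, one-sided Fisher's exact test, p = 0.000375), and Ctse was among the 2704 called lower (0.302 by chance, p = 0.302). With edgeR calls 5 genes were shared higher (0.769 by chance), 1 was shared lower (0.213 by chance) and 7 were opposite. With DESeq2 calls 25 were shared higher (7.31 by chance), 7 shared lower (11.3 by chance) and 79 opposite. The number of opposite calls by chance was not computed, so these counts do not show opposition between the populations. The difference between both log2 fold changes was at least 1 in size for 762 genes, 652 of them higher and 110 lower in Ttex cells (419 and 177 with upper-quartile scaling, and 376 and 225 with centring), and the interaction test called 865 of 11265 genes. That test pooled the spread over both populations, and the spread was larger in Ttex cells, so its p-values may be too small. Population and any batch of sorting or sequencing cannot be separated here.

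**Figure D3:**
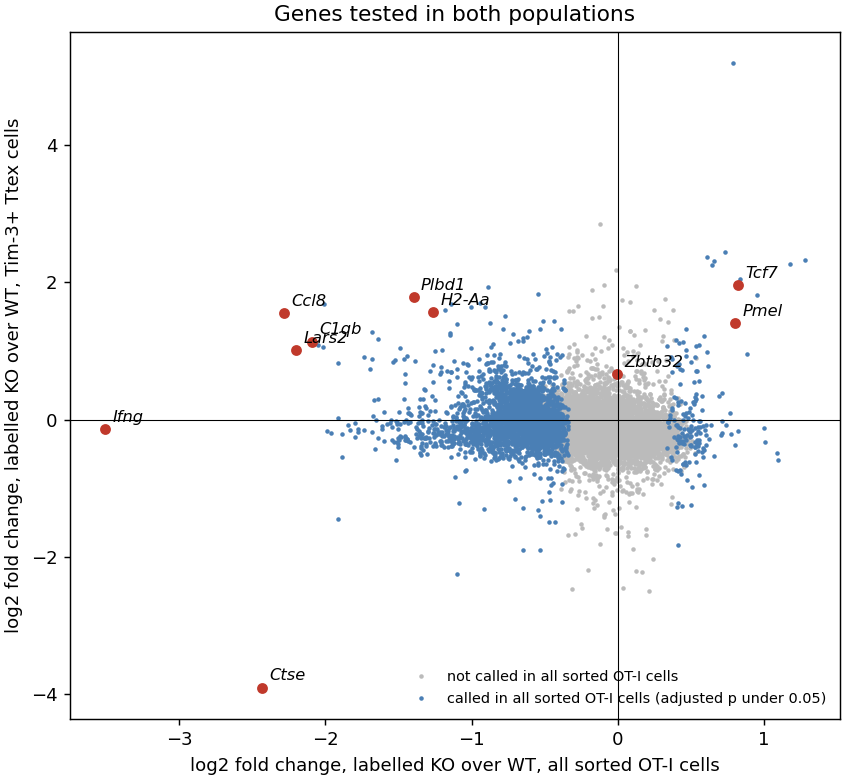
Log2 fold change (KO-labelled over WT-labelled) in all sorted OT-I cells (x axis) against Ttex cells (y axis), 1 point per gene tested in both; blue points were called in all sorted OT-I cells and 10 named genes are marked in red. Ctse is low on both axes (-2.43 and -3.90), Tcf7 and Pmel are high on both, and C1qb, Ccl8 and H2-Aa lie at the upper left.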

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

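The tests against under-counted genes, of the melanoma markers, of GC content with the library level kept and of chromosome segments with Ctse left out were chosen after the results were seen, as was the interaction test that selected the genes below. In that test (edgeR on recovered reads, adjusted p under 0.05) the KO against WT effect was called different between Ttex cells and all sorted OT-I cells. The test pooled the spread over both populations, although edgeR's common dispersion was 0.020 in all sorted OT-I cells and 0.048 in Ttex cells. Its p-values may therefore be too small for the Ttex part. Each value is the log2 effect in Ttex cells minus that in all sorted OT-I cells.

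Genes abundant in myeloid or other immune cells had positive differences: Ccl8 3.96, Il1b 3.84, Wfdc17 3.77, Foxp3 3.69, Plbd1 3.69, C1qb 3.14, C1qc 3.12, Tyrobp 3.11, C1qa 3.08, H2-Aa 2.71, Apoe 2.45, Lyz2 2.31, Fcer1g 2.24, Cd74 2.21 and Cst3 1.61. Effector genes differed by 3.25 for Ifng, 1.92 for Ccl1, 1.70 for Gzma and 1.14 for Klrc2. Signalling, stress and survival genes differed by 1.95 for Ier5, 1.92 for Atf3, 1.90 for Jund, 1.25 for Dusp2, 1.08 for Dusp5, 0.97 for Fyn and 1.0 for Mcl1. Interferon-induced Ifitm3 and Rtp4 differed by 2.81 and 1.49, and the mitochondrial or hypoxia genes Lars2, Cox6c, Ndufb3, Cox6b1, Ndufb5, Higd1a and Cox5a by 3.02, 1.36, 1.09, 1.08, 1.02, 0.96 and 0.87. Upk1a (1.85), Capns1 (1.44) and Usf2 (1.22), which lie near Zbtb32, and Ccr6 (1.68), Tcf7 (0.90) and Foxo1 (0.87) also had positive differences. Negative differences were found for Ctse (-1.48), Chpf2 (-1.49), Rasa3 (-1.18), Rrp12 (-1.17), Acly (-1.12), Pecam1 (-0.96) and Il4ra (-0.95).

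More genes were lower than higher in KO-labelled libraries of all sorted OT-I cells (2909 against 235). The GC test first chosen, a correction that also centres each library, left 991 lower, which met its bound for a GC cause, but centring without any GC term left 1146. With each library's level kept 2524 stayed lower. That version keeps the shift of the median gene and the first removes it, so neither can decide whether GC content caused it. Under-counting is argued against as the whole cause by 6.69 lower calls per higher call among 5900 genes with at least their read share in the Ttex table, but it stays open for part. The 3064 genes under that share held 1735 lower and 29 higher calls, but the share was taken over KO-labelled libraries too. A fall in those libraries helps to put a gene in that group, so this excess cannot measure under-counting. Scaling cannot be told apart from a real shift: median-ratio rescaling left 87.7% of calls lower and so met the bound set in advance against scaling, but it uses genes under the filter too and left the tested genes at a median of -0.19, while upper-quartile scaling left 61.1% lower, and a change in total RNA per cell was not tested.

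Macrophage markers were lower in KO-labelled libraries of all sorted OT-I cells, although OT-I cells had been sorted. A candidate explanation is a larger share of macrophage RNA in the WT-labelled libraries: of 23 tested macrophage and monocyte genes outside the first list, 19 were called lower and 0 higher (13 and 0 with centring), against 30.4% of all genes called lower. That list was chosen before its values were seen as a set, but after the fall of the first list and of some of its own genes, Wfdc17 among them. A general gain of RNA from other cells in the WT-labelled libraries was tested with the melanoma markers, 4 of 7 called higher in KO-labelled libraries. They lay apart from the macrophage markers (exact Mann-Whitney test, p = 0.00282). The bound first written, no melanoma marker lower, was not met (Apoe and Mlana, 2 of 7). The test treats genes as independent and was chosen after these markers had been seen. Foxp3 (-1.10) and Il1b (-1.18), markers of other immune cells at low values, were lower too, while 4 of 4 red blood cell genes were higher. The melanoma markers as a set therefore did not fall with the macrophage markers, but this cannot exclude a gain of RNA from other immune cells. In Ttex cells the second list had a median log2 fold change of 0.50, and an effect of genotype on these genes within T cells stays open.

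Ctse was lower in KO-labelled libraries of both populations, with larger changes than Tcf7 and Pmel, the other genes called in both. Ctse lies on chromosome 1, so a segment carried with the mutation on chromosome 7 cannot hold it. Within 10 Mb of Zbtb32, 0 of 128 genes moved the same way by 0.5 or more in both populations (one-sided Fisher's exact test, p = 1). As only 1.11% of other genes did, this count cannot decide whether such a segment is present. An effect of such a segment on Ctse was not tested. A congenic segment around Ptprc, the CD45 gene often used to tell donor cells apart, might carry a Ctse variant, as Ctse lies 6.46 Mb from it. As first worded the test counted Ctse itself and passed (3 of 54 genes, one-sided Fisher's exact test, p = 0.0217), and with Ctse left out, because it had raised the question, it did not (2 of 53 against 1.08% of others, Fisher's exact test, p = 0.114), so this explanation cannot be told apart on so few genes. The 2 genes were Lad1 (0.95 in all sorted OT-I cells and 1.82 in Ttex cells) and Rgs1 (-0.70 and -0.55). The same explanation stays open for them. Regulation by Zbtb32 stays open and was not tested.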

How the results depend on the processing

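Tests on recovered reads, centring, the GC corrections, and the edgeR correlation were added after the data were seen. In all sorted OT-I cells the main count of 3144 stayed within 1.5 times under the settings not given here, and it was 1933 with upper-quartile scaling, 1626 with the stricter filter, 1889 with a fold of at least 1.5, 1937 with the GC correction, 1995 with centring, 1365 in an edgeR fit of all 8 libraries, and 1602 to 2726 leaving out a library. For Ttex cells the main count of 3 became 15 with median-ratio rescaling, centring or edgeR, 12 with upper-quartile scaling, 17 with the stricter filter, 5 with pseudocount 5, 14 with the GC correction or limma-voom, 13 with the GC correction that kept library levels, 16 with the added 1 left in, 388 with DESeq2, 170 in the fit of all 8 libraries, 1 at an adjusted p under 0.01, and 0 to 26 leaving out a library. Without a filter limma called 0 Ttex genes, with 1805 at an unadjusted p under 0.05. With edgeR and DESeq2 size factors 2 remained. The stricter filter and the left-out libraries test fewer genes or samples, and the bound on fold or adjusted p keeps fewer of the same tests. For the other settings the cause was not tested. Same-numbered libraries are not stated to share recipients, and their deviations correlated by 0.299 in all sorted OT-I cells and 0.139 in Ttex cells over 2 pairs. With the replicate block Havcr2 and Zbtb32 were called in Ttex cells (adjusted p = 0.00435 and 0.00797), Gzmb in all sorted OT-I cells (3.4e-08) and, among other named genes of Ttex cells, Cd74 (3.02e-05) and H2-Aa (5.82e-05). The oxidative phosphorylation and IL-2 lists then passed camera in all sorted OT-I cells (0.000303 and 0.036), and the B cell set did not in Ttex cells (0.0642). With that block limma called 3836 and 844 genes, edgeR 5491 and 544, and the interaction test 2459 in place of 865. Genes whose effects differed by at least 1 numbered 1342 without the filter, which adds genes. The correlation of both effects was 0.0202 among genes called in either comparison and 0.133 with edgeR fold changes over 11094 genes, which changed the method and the gene set together. Of the lists, 0 passed in either comparison with an estimated correlation. In all sorted OT-I cells fry called 1 list one way and 14 in either direction, against 6 by camera, and in Ttex cells 5 one way. In either direction fry called further lists in Ttex cells, NK-type receptors (adjusted p = 0.00248) and cholesterol and fatty acid synthesis (0.00868) among them. No named gene that was called turned its direction. Of 367 values of named genes in all sorted OT-I cells with a library left out, 59 lost and 2 gained a call, and in Ttex cells 6 and 7 of 236.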

Other observations

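Ribosomal protein and mitochondrial genes, families chosen after their values were seen, were lower in KO-labelled libraries of all sorted OT-I cells and had positive medians without a call in Ttex cells. In all sorted OT-I cells 77 of 82 ribosomal protein genes were called lower in KO-labelled libraries (limma, median log2 fold change -0.81, and -0.57 with 43 lower after centring), and they took 4.70 and 4.37% of reads against 6.54 and 5.55% in WT-labelled libraries. In Ttex cells their median was 0.49 with 0 of 85 called, and 12.3 and 9.43% of reads against 9.49 and 6.79%. All 13 tested mitochondrially encoded genes were lower in all sorted OT-I cells (median -1.22, and -0.98 with 13 lower after centring), and the 33 tested in Ttex cells, most of them RNAs absent from the protein-coding table (median length 71 against 784), had a median of 0.62 with 0 called. With an estimated correlation the camera adjusted p of the wider sets of all symbols starting with Rpl, Rps or mt-, kinase genes or pseudogenes among them, was 0.978 in all sorted OT-I cells and 0.723 in Ttex cells, and the length decile with the shortest transcripts had medians of the same signs (-0.55 and 0.35). Nduf genes, which encode subunits of respiratory complex I, had 35 of 46 lower (median -0.66, and 10 lower after centring) and a median of 0.33 in Ttex cells. With upper-quartile scaling the 4 medians of ribosomal and mitochondrial genes kept these signs (-0.56, -0.96, 0.56 and 0.68).

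Chemokine genes (symbols starting with Ccl) were called lower in 11 of 14 tested members in all sorted OT-I cells, with a median of -1.15. This family stood first of the symbol families by camera (adjusted p = 4.04e-13), and not with an estimated correlation (adjusted p = 0.978). Macrophage markers, of cells that express many of these chemokines, had a similar median of -1.14, and in Ttex cells 12 Ccl genes had a median of 0.29 with 0 called.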
